A study of Mus musculus with 3 samples.

How the data were processed

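RNA came from 4T1 cells, a BALB/c mouse mammary carcinoma line, that carried GFP and had been implanted in the mammary pad of female mice. Per the labels, cancer cells were sorted by flow cytometry from the primary tumour (PCC), from the circulation (CCC) and from metastatic lung (MCC). Each group has 1 array, so there are 3 arrays in all, and how many mice stand behind an array is not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit, made into biotin-labelled cRNA with the Ambion MessageAmp kit and hybridised to Illumina mouse BeadChips.

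The main values are the deposited probe intensities, which the authors summarised in GenomeStudio per the submitters' processing notes (version not given in the sources used here). The file names no background step, but between 24.0% and 28.3% of the deposited intensities lie below 0, so background had been subtracted. A detection p-value was deposited for every probe on every array, per the file headers. The authors' second table of intensities is also deposited. Each of its columns was a straight line of the same array's intensities, with slopes of 0.926 (PCC), 0.865 (CCC) and 1.53 (MCC), offsets of 27.0, 10.3 and 9.62, and a largest residual of 0.0131. Its column medians were 42.9, 32.0 and 35.1. It is on a linear scale, its genes are not centred and its direction is that of the intensities. The between-array method that gave these lines is not stated.

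The table holds 25697 probes, of which 23978 have 1 gene symbol in the platform annotation, 0 have several and 1719 are unnamed here. Symbols were updated through the gene ID, and 23962 probes matched the mouse reference table (assembly GRCm38.p6, used for names only). No coordinates are given, because the build behind the array's annotation is not given in the sources used here.

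Background was corrected and arrays were normalized with the neqc function of limma 3.58.1 in R 4.3.3. It models background from negative controls inferred through the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was called detected at a detection p under 0.01. Each gene was represented by the probe with the highest mean log2 intensity among its detected probes, which left 9082 genes detected on at least 1 array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

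Differences are log2 intensities subtracted within a pair of arrays (CCC minus PCC, MCC minus PCC and CCC minus MCC). With 1 array per group there is no spread between replicates, no replicate check and no p-value between groups. Genes were counted by a fixed size of at least 2-fold among genes detected on both arrays of a pair. A gene detected on 1 array of a pair is given as a lower bound of its fold, against the higher of the lowest detected log2 intensity on the other array and the probe's own value there. The number of arrays limits the precision of every value.

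Before the data were examined, 30 gene lists were fixed, 21 of cell programs and RNA quality and 9 of other cell types a sort could hold. They name 657 genes, of which 587 have a probe. A list's median difference was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins. A list outside the central 95% is said to stand apart, which describes these arrays and is no test of the conditions. Members detected on neither array of a pair were left out. If lists were independent, 4.5 of the 90 list comparisons would lie outside by chance, and 45 did, 15 in CCC minus PCC, 14 in MCC minus PCC and 16 in CCC minus MCC. They are not independent, so 4.5 is no chance rate here. Oxidative phosphorylation is the union of the complex I, complexes II to IV and ATP synthase lists, and some other lists share genes. The differences in CCC minus MCC follow from those of the other pairs.

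The genes named in the text were also set by a rule fixed before the data were examined. It took, per pair, the 8 highest and 8 lowest genes detected on both arrays and the 3 largest bounds in each direction, leaving out symbols that are only clone, locus or model names. It also took the extreme members of each list and a fixed set of mitochondrial, epithelial and cell type genes. Of that fixed set, Pprc1 and Hbb-b1 have no probe matched here. Another 5 marker lists (adipocyte, lymph node, mammary epithelium, lung and liver) were written after the first results were seen.

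The counting and list steps were tested on simulated arrays built from the mean intensities and background spread, with noise of 0.1 on the log2 scale, for CCC minus PCC, with 11559 probes in the counting step. The changed probes were drawn only from bright probes detected on all 3 arrays. Of 50 probes set 4-fold higher, 100.0% passed the 2-fold size with a median log2 difference of 1.96. Of 50 set 2-fold higher, 38.0% passed, with a median of 0.97, and of 50 set 2-fold lower 40.0% passed, with a median of -0.97. All 50 set 4-fold lower passed, with a median of -1.94. Of the 11359 unchanged probes, 0.01% passed. Among 200 lists of 20 probes drawn from those 11359, 3.5% lay outside the central 95%, and after a shift of 0.35 all 100.0% lay above it. The noise was chosen and independent between probes, so these rates check the steps and are no error rates of the real arrays. On the real arrays, the CCC minus PCC differences of probes of the same gene lay a median of 0.235 apart.

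Alternatives fixed before the data were examined were no background correction, an offset of 50, scaling to the 75th percentile, no normalization between arrays, a detection p under 0.05, only genes detected on all 3 arrays, no filter, the mean of a gene's probes, the authors' own normalized intensities, and a 1.5-fold size. Normalizing PCC and CCC without MCC was added after the data were seen. Genes with near-identical copies (Lyz1 and Lyz2, the Ccl21 genes, the haemoglobin genes, the Mup genes) are uncertain, since a probe can read several copies.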

Results

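The transcriptomes of sorted 4T1 cancer cells from the primary tumour, the circulation and metastatic lung were measured on 1 array each. The series title places the question in mitochondrial biogenesis and oxidative phosphorylation during metastasis, under the coactivator PGC-1α. Of 25697 probes, 10532 (41.0%) were detected on the array labelled PCC, 11473 (44.6%) on the array labelled CCC and 11301 (44.0%) on the array labelled MCC. Mean probe intensity was 410 on PCC, 462 on CCC and 232 on MCC. Because genes of other cell types separated the arrays, as given with each comparison, every direction here is that of the array carrying a label. A wrong label of the array labelled MCC cannot be excluded with 1 array.

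The comparison of the circulating with the primary tumour array asks which genes differ between cancer cells in the blood and in the tumour they left. Genes of the respiratory chain were higher as a group on the array labelled CCC, while glycolytic and hypoxia-response genes were lower. Of 74 measured genes of oxidative phosphorylation, 68 were higher and 6 lower, with a median log2 difference of 0.35, at the 100.0th percentile of matched random lists. The differences were small, and 3 members reached 2-fold, the ATP synthase subunits Atp5o (2.53-fold) and Atp5j (2.06-fold) and the complex I subunit Ndufs8 (2.12-fold). Atp5o was dim, at a log2 intensity of 6.40 on PCC and 7.74 on CCC. On the same array the macrophage list was higher by a median of 2.32.

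Each part of the chain stood apart. The median was 0.34 over 33 genes of complex I, 0.40 over 25 genes of complexes II to IV and 0.28 over 16 ATP synthase genes. Sdhb of succinate dehydrogenase was 1.68-fold higher and the cytochrome oxidase subunit Cox7c 1.65-fold higher, while the assembly factor Cox15 was 1.25-fold lower. Cox5b and Cox4i1, also of cytochrome oxidase, were 1.32-fold and 1.24-fold higher. The 64 genes of the mitochondrial ribosome had a median of 0.12 (99.4th percentile), led by Mrpl36 (1.83-fold) and Mrps24 (1.65-fold). Genes of the TCA cycle lay inside the range of random lists, at -0.15, and so did the cytosolic ribosome, at 0.03.

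**Figure D1:**
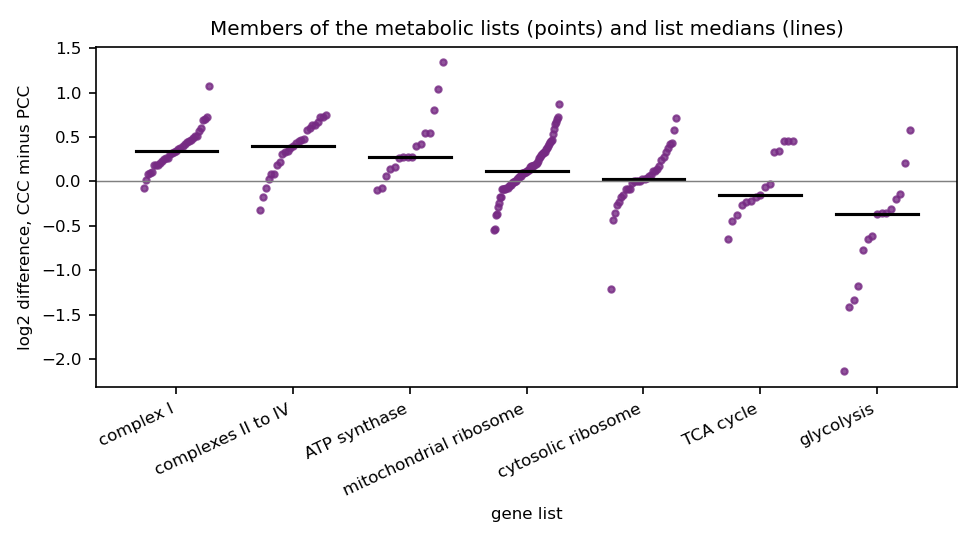
Log2 difference, CCC minus PCC (vertical axis), of each measured gene (points) in 7 metabolic and ribosomal lists (horizontal axis), with list medians as lines; 1 array per label. Medians of the respiratory chain lists lie between 0.28 and 0.40 and that of glycolysis at -0.37.

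The upstream regulators of mitochondrial biogenesis did not stand apart. Their 16 measured genes had a median of -0.06, at the 63.5th percentile, and 0 of them reached 2-fold. Ppargc1a, which encodes PGC-1α, was not detected on any array, with detection p-values of 0.531 (PCC), 0.482 (CCC) and 0.177 (MCC) from its probe. Ppargc1b, its relative, was detected on CCC and narrowly missed detection on PCC (detection p 0.0201), at least 1.71-fold higher on CCC. At a detection p under 0.05 it counts as detected on PCC as well. The nuclear receptor Esrra (1.01-fold lower), the transcription factor Nrf1 (1.18-fold lower) and the mitochondrial DNA packaging factor Tfam (1.09-fold higher) were at similar levels. Cytochrome c (Cycs) was detected on CCC and not on PCC, at least 1.63-fold higher.

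Glycolysis had a median of -0.37 over 15 genes (0.32nd percentile), with 4 at least 2-fold lower and 0 higher. Enolase 2 (Eno2) was 4.39-fold lower and the glucose transporter Slc2a1 2.65-fold lower, while phosphofructokinase Pfkp was higher by 0.58 on the log2 scale. Hypoxia-response genes had a median of -0.52 over 17 genes (0.04th percentile), from -1.05 among only the genes detected on all 3 arrays to -0.36 without normalization. The prolyl hydroxylase Egln3 was 2.72-fold lower and Ndrg1 2.66-fold lower, whereas Car9, a carbonic anhydrase, was 1.11-fold higher. Slc2a1 and Pdk1 (2.27-fold lower) belong to both the glycolysis and the hypoxia list, so these results are not independent. Immediate early genes, which respond to handling and stress, were also lower, with a median of -0.43 (0.32nd percentile), or -0.34 and inside the random range among only the genes detected on all 3 arrays, and the macrophage and lymphocyte lists were higher by medians of 2.32 and 2.75. Cell cycle genes differed little, with a median of -0.01 over 22 genes and 0 past 2-fold.

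The lists of macrophage, lymphocyte, endothelial and fibroblast markers had medians above the random range on the array labelled CCC. Of 13 measured macrophage genes 12 were higher and Cd14 was 1.07-fold lower, with 11 higher by at least 2-fold, among them Ms4a7 (14.0-fold), lysozyme Lyz2 (11.1-fold) and the complement gene C1qa (3.69-fold). Lymphocyte genes had a median of 2.75 over 8 genes (1.06 with no filter on dim probes, still above the range), with the T cell receptor component Cd3d 11.8-fold higher and the B cell gene Cd79b at least 8.81-fold higher. The pan-leukocyte gene Ptprc was at least 1.52-fold higher. Endothelial genes had a median of 1.05, with Pecam1 2.08-fold and Eng 2.94-fold higher, and fibroblast genes 1.42, with 8 of 12 genes higher, such as the collagens Col1a1 (4.32-fold) and Col3a1 (6.99-fold), and 4 lower, such as Pdgfrb (1.79-fold) and Pdgfra (1.57-fold). On PCC, Ms4a7 (5.97), Cd3d (6.03) and Col3a1 (6.16) lay near the lowest detected log2 intensity of 5.88, so the sizes of their folds are uncertain. With genes detected on 1 array set at their bounds, the lymphocyte, endothelial and fibroblast medians were 1.70, 0.95 and 1.23. Among only the genes detected on all 3 arrays the fibroblast median was 0.19, inside the random range. Neutrophil genes were lower, at -0.63 over 7 genes, with S100a8 and S100a9 1.55-fold and 1.69-fold lower. The neutrophil median was -0.38 at a detection p under 0.05 and -0.14 with no filter on dim probes, both inside the range. Red blood cell genes lay inside the range (-0.55 over 3 genes), haemoglobin Hba-a1 was 1.16-fold lower, the platelet chemokine Pf4 was 2.63-fold higher and platelet Ppbp was not detected on either array. The platelet list had a median of 0.95 over 2 genes, inside the range.

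Genes of the epithelial-mesenchymal transition list had a median of 0.35 over 16 genes (99.8th percentile), with 7 at least 2-fold higher and 0 lower. Smooth muscle actin Acta2 (10.5-fold) and S100a4 (5.01-fold) led it, both also made by stromal or myeloid cells, and fibroblast and macrophage lists were higher on the same array. The transcription factor Twist1 was 2.45-fold higher, Snai1 1.54-fold lower and vimentin (Vim) 1.31-fold higher. Twist1 was dim on PCC, at 5.98 against a lowest detected log2 intensity of 5.88. E-cadherin (Cdh1) was 1.62-fold higher, and the epithelial list did not stand apart (-0.02 over 7 genes).

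Across all genes, 361 were at least 2-fold higher and 268 lower on CCC than on PCC, of 7286 detected on both (8.63%), and 110 and 18 passed 4-fold. Of 1784 genes with several probes detected on both arrays, 2.3% had probe differences over 1 apart on the log2 scale. Besides Ms4a7, Cd3d, Lyz2 and Acta2, the highest were the chromatin organiser Satb1 (15.5-fold), the mast cell tryptase Tpsab1 (11.7-fold), the calcium pump Atp2a3 (11.4-fold) and Tbc1d10c (10.5-fold). The lowest were the growth factor Igf2 (15.8-fold), the lipopolysaccharide-binding protein Lbp (14.7-fold), the small heat shock protein Hspb1 (7.85-fold), the cytokine Il11 (6.80-fold), Itih2 (6.47-fold), metallothionein Mt2 (5.23-fold), the neutrophil chemokine Cxcl1 (5.14-fold) and lipocalin Lcn2 (5.04-fold). Glycam1, an L-selectin ligand of lymph node venules that the lactating mammary gland also makes, was detected on CCC and not on PCC, at least 47.7-fold higher. The scavenger receptor Scarf2 (at least 27.4-fold) and the lymph node chemokine Ccl21a (at least 27.2-fold) followed. Ggt7, Fetub and Popdc3 were detected on PCC and not on CCC, at least 4.24-fold, 3.59-fold and 3.53-fold lower. Background handling moved the lower count, to 164 with no background correction and 156 with an offset of 50. Between-array scaling moved the split, since without normalization 82.4% of the genes past 2-fold were higher on CCC, against 57.4% here.

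**Figure D2:**
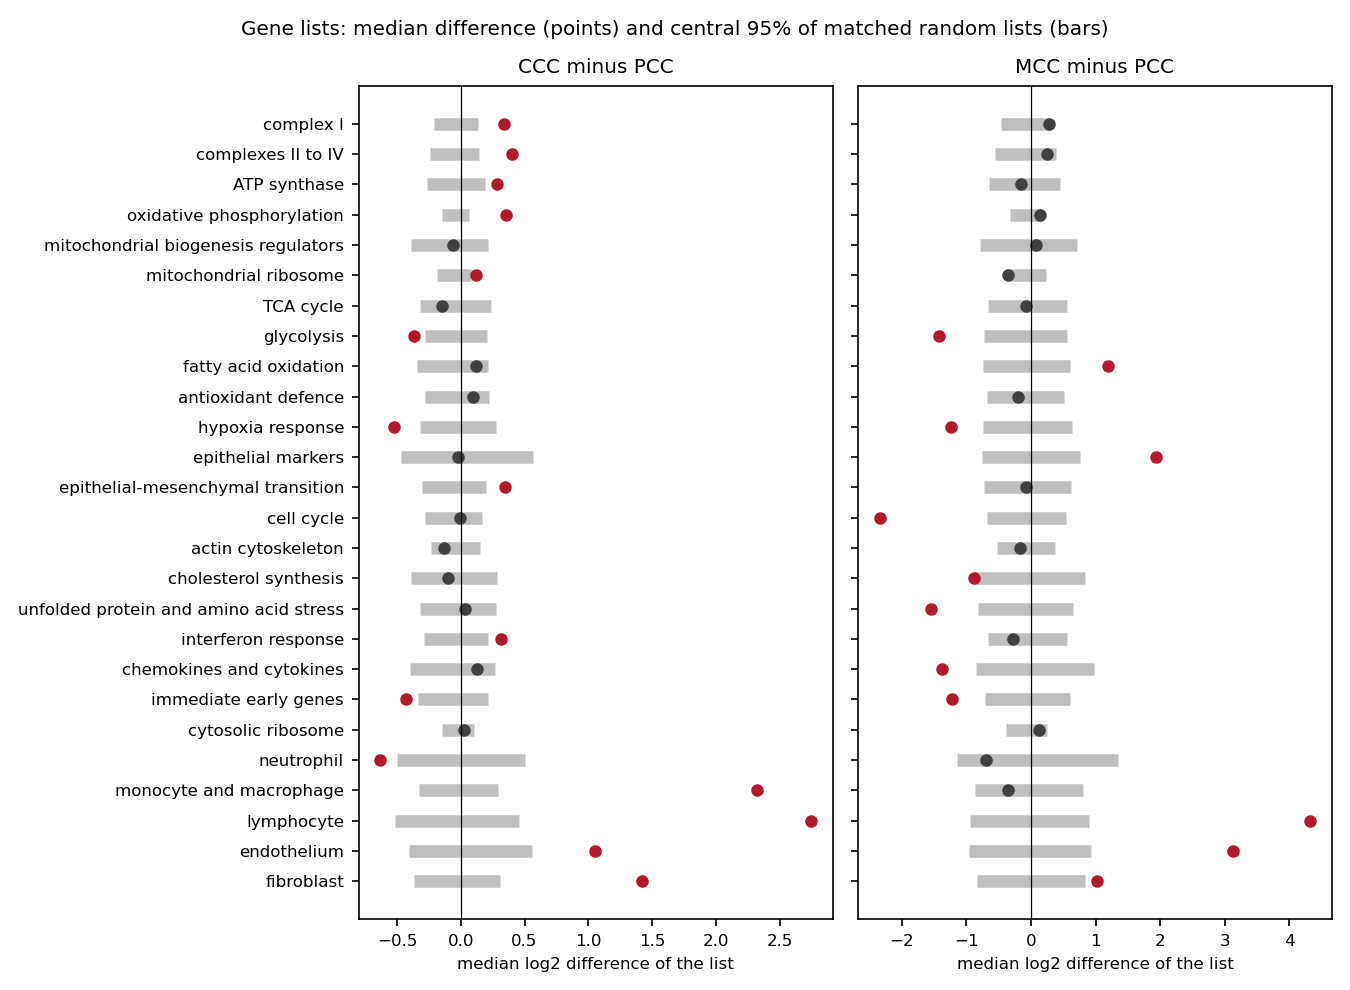
Median log2 difference (horizontal axis) of each gene list (vertical axis) for CCC minus PCC and MCC minus PCC; points are list medians, red where outside and dark grey where inside the grey bars, which span the central 95% of matched random lists. Lists with at least 5 measured genes in both pairs are drawn. Oxidative phosphorylation lies at 0.35 in the left panel and at 0.14, inside its bar, in the right.

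The comparison of the metastatic with the primary tumour array asks what differs between cancer cells in the lung and at the site of origin. It gave a far wider separation. On the array labelled MCC, genes of cell division, glycolysis, hypoxia and protein folding were lower, and genes of fat, lymphocytes, endothelium, epithelium and fatty acid oxidation were higher. Of 6829 genes detected on both arrays 967 were at least 2-fold higher and 1438 lower (35.2%). The correlation across genes was 0.737, against 0.938 for CCC with PCC, and genes are not independent replicates. Of 1560 genes with several probes detected on both arrays, 12.9% had probe differences over 1 apart on the log2 scale, so single-probe 2-fold values are uncertain.

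Cell cycle genes had a median of -2.34 over 22 genes, with 20 at least 2-fold lower and 0 higher. The mitotic kinase Aurka was 22.5-fold lower and Cdk1 16.5-fold lower. Glycolysis had a median of -1.42, with all 15 measured genes lower, hexokinase Hk2 by 10.9-fold and Slc2a1 by 10.3-fold. Hypoxia-response genes had a median of -1.23 over 16 genes. Egln3 was 18.2-fold lower and Car9 at least 20.7-fold lower, whereas the glycoprotein Stc2 was detected on MCC and not on PCC, at least 19.1-fold higher. On the same array the lymphocyte list was higher by a median of 4.32 and the endothelial list by 3.13.

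Fatty acid oxidation genes had a median of 1.20 over 15 genes, with 10 at least 2-fold higher and 0 lower, led by the thiolase Acaa2 (4.98-fold) and the carnitine carrier Slc25a20 (4.72-fold). Other probes of Acaa2 gave log2 differences of 0.81 to 1.09. Oxidative phosphorylation did not stand apart, with a median of 0.14 over 74 genes (95.9th percentile) that went both ways, 41 higher and 33 lower. Ndufs8 (2.42-fold) and Ndufs7 (2.41-fold) of complex I were higher, and Ndufc2 (2.42-fold) and Cox11 (2.48-fold) were lower. The median was 0.20 under 75th percentile scaling and 0.25 among genes detected on all 3 arrays, both outside the random range. Without normalization it was -0.67, also above the range (97.7th percentile), since the median of all genes was -0.75. Mitochondrial biogenesis regulators did not stand apart (0.09 over 16 genes). Ppargc1b was detected on MCC and not on PCC (detection p 0.0201 there), at least 6.82-fold higher, and Esrra was 1.95-fold higher. The fat genes given next were higher on the same array.

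Several genes of fat cells were bright on the array labelled MCC and undetected on PCC. Lipoprotein lipase (Lpl) was at least 246-fold higher and the lipid droplet gene Cidec at least 144-fold higher, while Plin1 was dimmer on MCC, at a log2 intensity of 7.53, and the milk protein Csn3 was 3.76-fold lower. The list of mammary gland and fat had a median of 7.68 over the 5 genes detected on either array. With no filter on dim probes, which adds undetected members, its median was 0.65, above the random range. All 10 measured lymphocyte genes were higher, with Cd3d 81.4-fold and Cd79b at least 79.0-fold higher. Cd3d was dim on PCC, at a log2 intensity of 6.03, so the size of its fold is uncertain. All 10 endothelial genes were at least 2-fold higher, among them Egfl7 (14.7-fold) and Pecam1 (9.32-fold). With genes detected on 1 array set at their bounds, the medians were 6.79 for mammary gland and fat, 4.03 for lymphocytes and 3.10 for endothelium. Hba-a1 was 5.94-fold higher. The lung surfactant gene Sftpc and the club cell gene Scgb1a1 were not detected on any array, and the lung epithelium list had a median of 1.53 over 6 genes, just outside the random range, led by the lipid transporter Abca3 (3.40-fold) and by Cyp2f2 (at least 2.88-fold), and Ager was at least 2.60-fold higher. That list lay inside the random range with no filter on dim probes, at 0.044. With genes detected on 1 array set at their bounds its median was 1.42, under the upper end of the main random range (1.52). Neutrophil genes went both ways, and the list did not stand apart (-0.70 over 7 genes, 10.1th percentile), with S100a8 and S100a9 28.4-fold and 29.6-fold lower and Ltf 51.5-fold higher. Macrophage genes went both ways, with Lyz2 9.45-fold higher and the macrophage receptor Adgre1 3.65-fold lower.

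**Figure D3:**
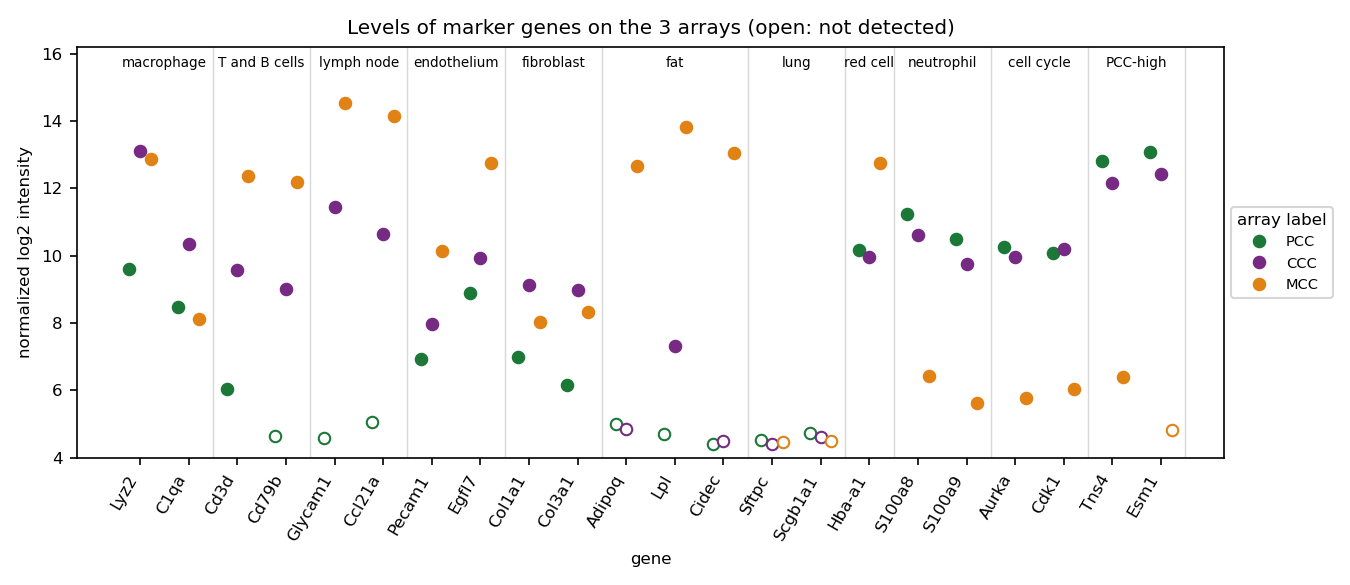
Normalized log2 intensity (vertical axis) of marker genes (horizontal axis) on the arrays labelled PCC (green), CCC (purple) and MCC (orange); open circles are not detected, and each point is 1 array. The fat gene Cidec is bright on MCC (13.05) and undetected on PCC and CCC, the fat gene Lpl is detected on CCC (7.33), and lung Sftpc is undetected on all 3 arrays.

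Epithelial genes had a median of 1.94 over 19 genes, of which 6 were detected on PCC and 19 on MCC. The tight junction gene Cldn4 was 25.6-fold higher, the splicing factor Esrp1 at least 21.0-fold higher and Cdh1 4.32-fold higher, while the junction protein Tjp1 was 3.53-fold lower and the keratin Krt8 1.78-fold lower. With genes detected on 1 array set at their bounds the median was 0.93, and among only the genes detected on all 3 arrays it was -0.32. The epithelial-mesenchymal transition list did not stand apart (-0.08). Acta2 was 30.4-fold higher and Zeb1 at least 10.6-fold higher, but Snai1 was 9.67-fold, the metalloprotease Mmp3 17.2-fold and Vim 2.22-fold lower.

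The highest genes on MCC over PCC were Satb1 (113-fold), Tbc1d10c (95.1-fold), the amino acid oxidase Il4i1 (86.9-fold), Cd3d, Arhgap45 (78.1-fold), Atp2a3 (76.9-fold), the lymphocyte receptor Cd27 (65.7-fold) and lactoferrin Ltf (51.5-fold). Glycam1 and Ccl21a were at least 402-fold and 307-fold higher. The lowest were the focal adhesion gene Tns4 (84.6-fold), the nuclear receptor Nr2f1 (69.5-fold), matrix Gla protein Mgp (61.4-fold), the cytokinesis gene Anln (54.0-fold), galectin Lgals7 (49.0-fold), the ligand Wnt7b (41.1-fold), the pyrophosphate transporter Ank (41.0-fold) and the protease inhibitor Slpi (40.4-fold). Esm1, Ecrg4 and the cytokine Tslp were at least 178-fold, 55.1-fold and 52.3-fold lower. The split depended on scaling. Of the genes past 2-fold 40.2% were higher here, 56.7% under 75th percentile scaling and 14.7% without normalization, as the median of all genes went from -0.16 to 0.12 and -0.75.

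The comparison of the circulating with the metastatic array sets the label from blood against the label from lung. Cell division and glycolysis genes were higher on the array labelled CCC, and fat, lymphocyte, endothelial and epithelial genes were lower. Cell cycle genes had a median of 2.25 over 22 genes, all higher, with Aurka 18.3-fold and Cdk1 18.1-fold higher. Glycolysis had a median of 0.91 over 15 genes, with Hk2 4.30-fold and Slc2a1 3.89-fold higher. The mitochondrial ribosome had a median of 0.52 over 64 genes (100.0th percentile), with Mrpl13 4.11-fold higher, and oxidative phosphorylation did not stand apart (0.14, 86.0th percentile). Fatty acid oxidation had a median of -1.33 over 16 genes, with Decr1 4.56-fold lower. Ppargc1b was 3.98-fold and Esrra 1.97-fold lower on CCC.

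Macrophage genes were higher on CCC than on MCC by a median of 2.24 over 13 genes, with Adgre1 20.3-fold and the mannose receptor Mrc1 12.2-fold higher. Fibroblast genes had a median of 0.73 over 12 genes, with Col1a2 5.57-fold higher and Thy1 5.57-fold lower, and that list lay inside the random range under 75th percentile scaling, at 0.52. Lymphocyte genes had a median of -2.42, endothelial genes -2.13, epithelial genes -1.96 and the list of mammary gland and fat -6.50 (-0.60 with no filter on dim probes). The epithelial median was -1.23 with genes detected on 1 array set at their bounds and 0.008 among only the genes detected on all 3 arrays. Red blood cell genes had a median of -2.10 over 3 genes, with Hba-a1 6.91-fold lower. Their median was -1.28 at the bounds, and -1.28 with an offset of 50 and -0.26 with no filter, where it lay inside the range.

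Of 7313 genes detected on both arrays 1211 were at least 2-fold higher on CCC and 1262 lower (33.8%). Of 1670 genes with several probes detected on both arrays, 17.3% had probe differences over 1 apart on the log2 scale. The highest were Tns4 (53.7-fold), Nr2f1 (52.1-fold), Anln (46.9-fold), Slpi (39.7-fold), Mgp (35.3-fold), arginase Arg1 (33.6-fold), the metalloprotease inhibitor Timp1 (33.2-fold) and Lgals7 (32.7-fold), with Esm1, the noradrenaline transporter Slc6a2 and Tslp at least 115-fold, 40.1-fold and 30.1-fold higher. The lowest were the growth factor Ptn (103-fold), Lpl (90.3-fold), cysteine dioxygenase Cdo1 (70.6-fold), the amine oxidase Aoc3 (37.2-fold), Igfbp5 (34.0-fold), Sult1a1 (33.4-fold), Ltf (31.3-fold) and the glutamate transporter Slc1a3 (31.1-fold). Cyp2e1, the carboxylesterase Ces1d and the urinary protein gene Mup2 were detected on MCC and not on CCC, at least 311-fold, 273-fold and 185-fold lower. Of the genes past 2-fold 49.0% were higher on CCC here, 35.3% under 75th percentile scaling and 88.1% without normalization.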

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

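No test was possible for these genes, since each label has 1 array, and the tests of the pattern on the array labelled MCC were chosen after the result was seen, that of the added lists included. Of 6753 genes detected on all 3 arrays, 249 were at least 2-fold higher on both CCC and MCC than on PCC and 112 lower on both, where independent differences would give 48.4 and 44.7. Another 24 were higher on CCC and lower on MCC and 10 the reverse, against 72.5 and 29.8. Both differences share the PCC array, which by itself favours shared directions. Among the genes with opposite directions, 5 belong to a fixed list. The macrophage genes Adgre1 and Mrc1 had log2 differences of 2.48 and 2.5 on CCC and of -1.87 and -1.11 on MCC. The cytokines Csf1 and Il1b had 1.54 and 1.49 on CCC and -1.37 and -1.30 on MCC. S100a4 had 2.33 on CCC and -1.35 on MCC. These differences were not tested.

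The array labelled MCC carried bright genes of fat, lymphocytes and endothelium beside low cell cycle genes. Lung tissue stays open, since of 14 lung epithelium genes with a probe 5 were detected on that array, Cyp2f2, Ager and Sftpd among them and on neither other array, while Sftpa1, Sftpb, Sftpc, Scgb1a1 and Scgb3a1 were not detected on any array. Tissue of the mammary fat pad with a lymph node may be a source of this RNA, although the sort for GFP should remove it. Added lists of adipocyte, lymph node and mammary epithelium genes lay above the central 95% of random lists in 3 of 3 cases, with medians of 2.85, 4.48 and 2.5, but these cell types were chosen because they had been seen on this array, so the lists restate the pattern and do not support that source. A wrong label of this sample cannot be told apart from it either, because few lung genes would follow from a sort as well as from another sample, and neither can a change within the metastatic cancer cells, the biological alternative, with 1 array of sorted cells and no array of normal mammary pad used here.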

How the results depend on the processing

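Normalizing PCC and CCC without MCC was chosen after seeing the data, and the other settings were fixed before. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Over the alternatives, 784 of the list values kept their side of the random range, and those outside it kept their direction. Another 15 newly stood apart and 30 no longer did. A further 5, which stood apart in the main or the alternative processing, reversed direction. Lists inside the range in both could change sign uncounted, such as the TCA cycle in CCC minus PCC (-0.15 here, up to 0.11). Of the counts, 46 stayed within 1.5 times and 16 did not. Of the 45 list medians outside the random range, 34 moved by over 1.5 times in at least 1 setting. Oxidative phosphorylation in CCC minus PCC ranged from 0.34 to 0.57. Except where a filter or an array-wide shift is named, the cause was not tested. Without normalization the arrays keep their brightness, so genes higher and lower numbered 567 and 121 (CCC minus PCC), 473 and 2745 (MCC minus PCC) and 3163 and 429 (CCC minus MCC). A 1.5-fold size, which passes more genes by construction, gave 756 and 1046, 1612 and 2256, and 2002 and 2053. With no filter 720 genes were higher in CCC minus PCC and 2014 in MCC minus PCC. Lower genes in CCC minus PCC numbered 164 with no background correction and 156 with an offset of 50. Without normalization, the array-wide shift reversed the medians of oxidative phosphorylation (-0.67) and complex I (-0.47) in MCC minus PCC and the cytosolic ribosome (0.80) in CCC minus MCC, although their percentiles among lists shifted alike (97.7, 99.2 and 2.11) stayed high, high and low, and in CCC minus MCC the genes Ndufa10 (0.10) and Sod1 (0.21). There, the epithelial-mesenchymal transition list newly stood apart in CCC minus MCC (1.53), and fibroblast (1.57) and immediate early genes (1.19) in CCC minus MCC and lung epithelium (0.86) in MCC minus PCC no longer did. With 75th percentile scaling, complex I (0.41) and oxidative phosphorylation (0.20) newly stood apart in MCC minus PCC, as did the cytosolic ribosome (-0.25) and the epithelial-mesenchymal transition list (0.48) in CCC minus MCC, while fibroblast (0.52) and immediate early genes (0.14) in CCC minus MCC and lung epithelium (1.74) in MCC minus PCC no longer did. With the authors' values, the cytosolic ribosome (-0.018) stood apart in CCC minus MCC and fibroblast (0.85) did not. With a detection p under 0.05, fibroblast in CCC minus MCC (0.73) and neutrophil in CCC minus PCC (-0.38) no longer stood apart. With the mean of the probes, the epithelial-mesenchymal transition list in CCC minus MCC (0.84) did and lung epithelium in MCC minus PCC (1.06) did not. With no background correction, cholesterol synthesis in MCC minus PCC (-0.70) and immediate early genes in CCC minus MCC (0.51) fell inside. With an offset of 50, chemokines (0.52), immediate early genes (0.47) and red blood cell (-1.28) in CCC minus MCC and cholesterol synthesis (-0.66) in MCC minus PCC fell inside, and lung epithelium (-0.86) in CCC minus MCC stood apart. With no filter, the epithelial-mesenchymal transition list (0.42) in CCC minus MCC and the mitochondrial ribosome (-0.32) in MCC minus PCC stood apart, and immediate early genes (0.16) and red blood cell (-0.26) in CCC minus MCC, lung epithelium (0.044) in MCC minus PCC and neutrophil (-0.14) in CCC minus PCC did not. Keeping only genes detected on all 3 arrays removes members absent from an array. This reversed the epithelial list in MCC minus PCC (-0.32) and CCC minus MCC (0.008). Standing apart ended for chemokines (0.29), cholesterol synthesis (0.41), fibroblast (0.73) and immediate early genes (0.16) in CCC minus MCC, for chemokines (-0.62), cholesterol synthesis (-0.66), fibroblast (0.62) and lung epithelium (1.62) in MCC minus PCC, and for fibroblast (0.19) and immediate early genes (-0.34) in CCC minus PCC. It began for chemokines (0.81) in CCC minus PCC, for complex I (0.29), oxidative phosphorylation (0.25) and red blood cell (1.65) in MCC minus PCC, and for the epithelial-mesenchymal transition list (0.84) in CCC minus MCC. Signal over background limits dim genes on every array. The array labelled MCC had a mean intensity of 232 against 410 on PCC. Its inferred background spread was also lower (8.47 against 11.5), and more of its probes were detected (44% against 41%).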

Other observations

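The tests of blood cells, of a smaller share of the MCC mixture, of short mRNAs and of other cell types were chosen after the result was seen. On the array labelled CCC, interferon-response genes stood above matched lists against PCC, with a median of 0.31 over 20 genes, led by the chemokine Cxcl10 (1.97-fold) and the immunoproteasome subunit Psmb9 (1.82-fold), and the macrophage and lymphocyte lists were higher on the same array by medians of 2.32 and 2.75. Immediate early genes were lower, with a median of -0.43 over 17 genes (0.32nd percentile), of which 7 were at least 2-fold lower, Atf3 by 3.21-fold and Fosb by 2.83-fold. Among only the genes detected on all 3 arrays their median was -0.34, inside the random range. Chemokine and cytokine genes went both ways on CCC, with Icam1 3.79-fold and Ccl5 2.95-fold higher and Cxcl1 lower, and the list did not stand apart (0.12). Its median depended on the filter, at -0.12 with no filter and 0.81, above the range, among only the genes detected on all 3 arrays. Fatty acid oxidation (0.12), antioxidant defence (0.10), actin cytoskeleton (-0.14), cholesterol synthesis (-0.10), protein folding stress (0.03), platelet (0.95), lung epithelium (0.53) and mammary gland and fat (0.32) did not stand apart in CCC minus PCC.

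On the array labelled MCC, genes of protein folding and amino acid stress had a median of -1.54 against PCC over 12 genes, with the glutathione-degrading enzyme Chac1 at least 19.5-fold and the chaperone calreticulin (Calr) 7.01-fold lower. Cholesterol synthesis had a median of -0.89 over 12 genes, with squalene epoxidase Sqle 16.6-fold lower. That list lay inside the random range with no background correction (-0.70), with an offset of 50 (-0.66) and among genes detected on all 3 arrays (-0.66), and its median at the bounds was -0.66. Immediate early genes had a median of -1.21 and chemokines and cytokines of -1.37, at the bounds -0.89 and -0.86, and the chemokine median among genes detected on all 3 arrays was -0.62, inside the range. Against the direction of these lists, Klf2 was 5.88-fold and Icam1 20.9-fold higher. Interferon-response genes did not stand apart (-0.27), but Oasl2 was 8.52-fold and Isg15 5.65-fold lower. Among the added lists, written after the pattern was seen, lung genes had a median of 1.90 over 4 measured genes and liver genes of 1.60 over 2, both inside the random range in MCC minus PCC. In CCC minus PCC the lymph node list had a median of 2.57 over 14 genes, the adipocyte list of 0.07 over 3 and the lung list of 1.24 over 3. The lymph node list stood above the range, the lung list also did, at the 98.2nd percentile, and the adipocyte list did not.

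The immune and stromal genes on the array labelled CCC were set against neutrophils, red cells and platelets in the sort, which would raise their own genes. The neutrophil list had a median of -0.63 in CCC minus PCC, but -0.38 at a detection p under 0.05 and -0.14 with no filter, both inside the random range, and the red blood cell list (-0.55) lay inside it too, so a share of these cells cannot be told apart, since genes such as S100a8 and Hba-a1 were already bright on PCC. For platelets, 2 of 9 genes with a probe were detected on CCC, Pf4 higher than on PCC but Ppbp undetected, which leaves them open. A smaller share of the MCC mixture, added to RNA like that on PCC, would leave macrophage genes between their PCC and MCC levels. Their median was higher than both, by 2.32 in CCC minus PCC and 2.24 in CCC minus MCC. Such a share would also lower fat and lymphocyte genes alike if both were absent from PCC. In CCC minus MCC the 4 fat genes bright enough to tell (Adipoq, Lpl, Cidec and Pparg) lay at -3.79 or below, Lpl at -6.50. The 10 lymphocyte genes lay at -3.17 to -0.71, but 5 of them were detected on PCC, where that RNA would hold their level up. The comparison therefore rests on Cd2, Cd79a and Cd79b, detected on CCC and not on PCC, since Cd4 and Ms4a1 were detected on neither. Another 7 dimmer fat genes such as Plin1 (-1.99 at its bound) lie too near the floor. Fibroblast and endothelial genes, macrophage and lymphocyte RNA from another source, and a change within the circulating cancer cells stay open.

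The higher oxidative phosphorylation genes on the array labelled CCC were weighed against measurement and mixture. The list's median ran from 0.34 with no filter to 0.57 without normalization. Its gap above the upper end of the random range was 0.274 at the lowest, against 0.29 in the main processing. This argues against the background correction and filtering applied here as the cause. The background subtraction made before deposition is part of every setting, so it was not tested. A single scaling factor per array shifts all genes alike and cannot move that gap. A shift of all short abundant mRNAs would raise the cytosolic ribosome, whose median was 0.028, and between -0.017 and 0.157 over the settings. Those genes were brighter, at a median level of 13.59 on PCC against 10.8 for oxidative phosphorylation. A shift limited to short mRNAs of lower brightness was therefore not tested. RNA of other cell types may contribute, since macrophage genes were higher by a median of 2.32 on that array, but the respiratory chain levels of such cells were not measured here. This cannot be told apart from a difference within the cancer cells, which is the biological explanation the design names.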
